A study of Mus musculus with 6 samples.

How the data were processed

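Messenger RNA was profiled by paired-end Illumina sequencing in mouse embryonic stem cells (ESCs) that, per the labels, lack Dgcr8. Per the labels the starting material was total RNA extracted with Trizol; whether polyadenylated RNA was selected is not given in the sources used here. Dgcr8 is a partner of Drosha in the nuclear step of microRNA maturation, so cells without it make no canonical microRNAs. Dgcr8 mRNA was not absent from the table, and gene-level values cannot show whether a transcript is intact. The 6 libraries form 3 groups of 2, named CTR, miR-294 and siMbd2 after the transfected RNA, and all were taken 48 h after transfection. The labels give a dose of 50 nM for microRNA mimics and siRNAs. What the CTR wells received is not stated, and the deposited table calls them mock. The labels do not say whether the replicates were separate cultures, and each sample is described as the average of a pair of sequencing lanes.

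The deposited table holds 1 RPKM value (reads scaled to transcript length and to the mapped reads of the library, per the file headers) for each gene and library, to 2 decimals. The authors' notes name CASAVA 1.7, STAR 2.3.0, Cufflinks (version not given in the sources used here) and the mm10 build, without saying which step each tool did. The gene annotation and the rule by which genes were listed are not given in the sources used here. The table also holds, per the file headers, a fold column for each treatment, which is the authors' ratio of mean RPKM over CTR. Recomputed ratios lay within 5% plus 0.01 of the deposited ones for 99.85% of genes for miR-294 and 99.79% for siMbd2, and every other gene had a CTR mean of at most 0.1 RPKM. The table has 13743 entries and 13721 distinct gene symbols, 19 of which occur on several entries. RPKM values carry no read counts, so the depth of each library is unknown and no counting error can be given.

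Values were analysed as log2(RPKM + 1). Genes with a mean of at least 1 RPKM over the 6 libraries were tested, 11428 in all. This scale understates fold changes of genes at low RPKM, so mean RPKM values are given beside log2 changes. One linear model with 3 groups was fitted in limma 3.58.1 (R 4.3.3), with an intensity trend in the empirical Bayes step, 3 residual degrees of freedom and 5.38 prior degrees of freedom. All tests were two-sided unless stated. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a contrast were called higher or lower, and rose, fell and changed refer to these calls. The p-values measure the spread between these libraries only. An exact permutation test of 2 libraries against 2 cannot give a p under 0.333, so every call rests on the shared estimate of spread in limma. The planned unit was FPKM; the table holds RPKM, and the same test was used on it. The alternatives that needed a count table were not run.

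The comparisons, tests, alternatives, 33 gene lists and the rule for named genes were fixed before the data were examined. The rule takes, per contrast, the 10 highest and 10 lowest log2 changes among called genes whose 2 libraries of one group both lie beyond those of the other and whose higher group has a mean of at least 5 RPKM, a fixed set of 15 genes from Mbd2 to Nanog, and up to 4 members of each list described. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 33 lists of a contrast. Fry tests whether a list's genes move on balance in one direction, without comparing them with other genes. Per list, members were also counted after adjustment over the list alone. Of the 33 lists, camera with the preset correlation called 9, 5 and 13 in miR-294 vs CTR, siMbd2 vs CTR and miR-294 vs siMbd2. With an estimated correlation none was called, and the lowest adjusted p was 0.541, 0.932 and 0.412. Fry called 22, 13 and 23. Loss of a call with an estimated correlation does not by itself show that a list's genes are correlated. For the cell cycle inhibitors in miR-294 vs CTR the estimate was -0.045, below the preset 0.01. Their unadjusted camera p still went from 0.0036 at the preset to 0.056. For lists with a higher estimate, such as the ribosomal proteins (0.656), correlation was not excluded as a cause of the loss. Below, a list is said to be called or not by camera at the preset correlation unless fry is named. A list given as not called may thus be called by fry. The median of a list and its camera test differed in sign for 6, 4 and 7 lists, none of them called.

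Sites for miR-294 were sought in the longest annotated 3' UTR of each gene (GENCODE vM21, GRCm38, the same assembly as mm10), with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3; plots used matplotlib 3.10.9. The site classes were the 8-base match AGCACTTA and the 7-base matches AGCACTT and GCACTTA. A 3' UTR was found for 11235 of the tested genes (98.3%), and genes without one were left out of site tests. Overlap between the treatments was compared with the product of the gene shares and with 100 simulations of unchanged groups set against the same CTR libraries.

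On simulated data with planted changes in 50 genes per size, the test recovered 32% of 1.25-fold, 98% of 1.5-fold and 100% of 2-fold and 4-fold changes, and 15 of its 180 calls (8.33%) were false. A planted list was found with an adjusted p of 1.5e-107, or 0.00392 with an estimated correlation, and no other list was called. The simulated genes varied independently of each other and equally in all groups. In the data the estimated correlation within a list reached 0.958 (mitochondrially encoded genes). The simulation thus does not give the rate of false list calls for correlated genes. Alternatives changed the pseudocount, the filter, the scaling between libraries (median of ratios, quantile normalization), the trend and robust options, the libraries in the model, a replicate block, the thresholds, the 3' UTR used and each library in turn. A 2-fold threshold, fold thresholds under other scalings, a run without genes listed at 0 in any library, a run without genes that hold GAGCGAG in the 3' UTR and a split of the CTR libraries between the contrasts were added after seeing the data. Where a library was left out, the remaining library of that group was assumed to vary like the other groups.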

Results

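Messenger RNA was measured in mouse ESCs described as Dgcr8-deficient 48 h after transfection, in 3 groups of 2 libraries: CTR, miR-294 and siMbd2. miR-294 belongs to the miR-290 family, the most abundant microRNAs of mouse ESCs, which cells without Dgcr8 cannot make. Mbd2 encodes a methyl-CpG binding protein of the NuRD repressor complex and is a described target of this family. The RPKM values of all listed genes summed to 450520 and 429460 in the CTR libraries, 493079 and 488568 in miR-294, and 470333 and 464663 in siMbd2. These sums are not read depth, which is unknown. The median absolute difference between replicates was 0.136 (log2) in CTR, 0.063 in miR-294 and 0.060 in siMbd2, so the CTR pair was the noisiest. The mitochondrially encoded genes took 3.03% and 4.13% of the summed RPKM in the CTR libraries, 2.53% and 2.68% in miR-294, and 3.27% and 3.38% in siMbd2. Below, values after ± are standard deviations of RPKM over the 2 libraries of a group (n = 2).

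Mbd2 itself was lower in every treated library than in every CTR library. Its mRNA (chromosome 18, 70568189 to 70626131, plus strand, GRCm38) stood at 26.8 and 27.9 RPKM in the CTR libraries, 11.3 and 12.3 in miR-294, and 7.33 and 6.34 in siMbd2. It fell by 1.86 on the log2 scale with siMbd2 (SE 0.087, adjusted p = 5.05e-05) and by 1.15 with miR-294 (adjusted p = 1.36e-05), and was 0.71 higher with miR-294 than with siMbd2 (adjusted p = 2.23e-04). The longest 3' UTR of Mbd2 holds the 8-base miR-294 match AGCACTTA at position 289 of 480 bases (chromosome 18, 70625940 to 70625947).

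The comparison of miR-294 with CTR asks what the microRNA does to mRNA levels in cells that lack it. Lin28a, which encodes an RNA-binding protein that blocks let-7 maturation, rose from 4.93 ± 0.72 to 91.0 ± 0.30 RPKM (log2 change 3.96, adjusted p = 3.1e-07). Myc, the growth-promoting transcription factor, rose from 2.12 ± 0.40 to 26.5 ± 0.69 RPKM (log2 3.14, adjusted p = 1.14e-06), and Dnmt3l, a cofactor of the de novo DNA methyltransferases, from 71.9 ± 0.47 to 414 ± 3.87 RPKM (log2 2.51). Msln, which encodes the cell-surface protein mesothelin, fell from 68.4 ± 9.29 to 8.70 ± 0.18 RPKM (log2 -2.83), and Psmb8, an immunoproteasome subunit, from 9.51 ± 1.71 to 0.74 ± 0.39 RPKM (log2 -2.61). Of 17 described targets of the family 16 fell, and of 40 Myc-responsive genes 35 rose.

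The other genes with the largest increases were Calca (1.83 ± 0.39 to 33.8 ± 0.36 RPKM), Spink3 (0.06 ± 0.09 to 10.9 ± 0.81), Eras (3.76 ± 0.24 to 30.3 ± 1.33), Bmp4 (0.77 ± 0.10 to 9.90 ± 0.66), E130012A19Rik (35.9 ± 0.57 to 207 ± 6.39), Soga3 (0.56 ± 0.01 to 7.24 ± 0.37) and Pla2g1b (3.65 ± 1.61 to 22.5 ± 0.24). Eras encodes a constitutively active Ras-like protein of ESCs, and Bmp4 a secreted morphogen. Among the largest decreases stood Trim47 (14.8 ± 3.83 to 1.27 ± 0.08 RPKM), Mmp23 (31.1 ± 7.73 to 3.86 ± 0.05), Erap1 (10.6 ± 1.07 to 1.03 ± 0.13), Aldh1b1 (27.5 ± 3.75 to 4.02 ± 0.33), Zbp1 (16.1 ± 1.56 to 2.07 ± 0.27) and Lrrc31 (22.9 ± 3.46 to 3.32 ± 0.47). Erap1 trims peptides for antigen presentation, and Zbp1 is a sensor of left-handed nucleic acids. A pair of predicted genes was listed at 0 with miR-294. Gm10351 read 16.5 and 28.3 RPKM in CTR and 0 in the other 4 libraries. Gm21028 read 19.5 and 16.6 RPKM in CTR, 0 in both miR-294 libraries, and 19.3 and 0 in siMbd2; near-identical gene copies make the assignment of reads to such genes uncertain.

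**Figure D1:**
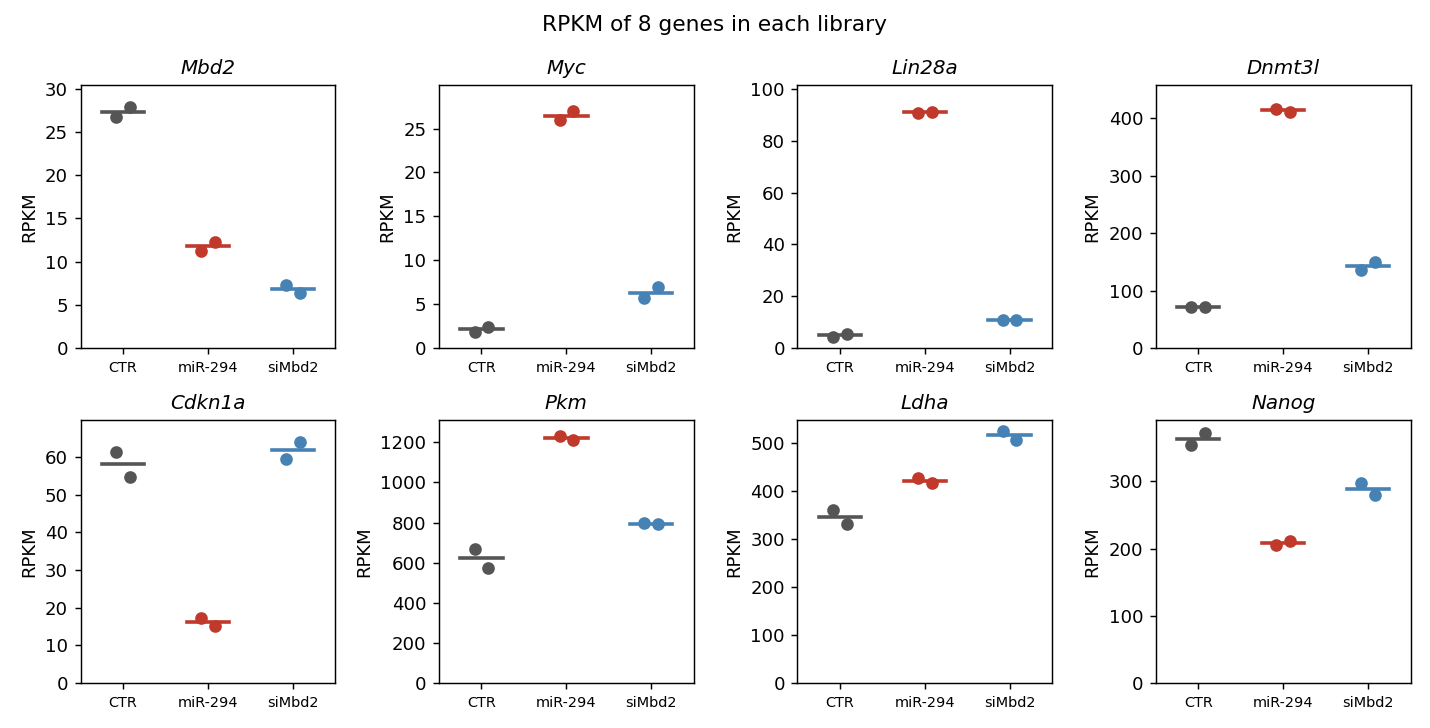
RPKM (vertical axes, linear, from 0) of Mbd2, Myc, Lin28a, Dnmt3l, Cdkn1a, Pkm, Ldha and Nanog in each of the 6 libraries, by group; points are libraries and horizontal lines are group means. Mbd2 was lower in all 4 treated libraries than in both CTR libraries, and Myc and Lin28a were highest with miR-294.

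Of 17 described targets of the miR-290 family, 16 fell and none rose with miR-294, with a median log2 change of -1.21 (adjusted p = 4.60e-07). Adjusted over the list alone 16 fell, and the list had adjusted p = 0.541 with an estimated correlation. Dazap2 fell from 112 ± 0.39 to 28.7 ± 0.79 RPKM. The Nodal inhibitors Lefty1 (93.3 ± 18.1 to 22.9 ± 1.97 RPKM) and Lefty2 (log2 -1.91) fell, as did the Hippo kinase gene Lats2 (log2 -1.46), the apoptotic protease gene Casp2 (-1.21) and Tgfbr2 (-1.27). Of 9 cell cycle inhibitors, 8 fell and 1 rose, the same numbers adjusted over the list alone. The list had adjusted p = 0.0147, and adjusted p = 0.541 with an estimated correlation, although the estimate (-0.045) was below the preset 0.01. Cdkn1a, which encodes the kinase inhibitor p21, fell from 58.1 ± 4.70 to 16.2 ± 1.47 RPKM, Rbl2, a retinoblastoma relative, from 8.98 ± 0.11 to 2.42 ± 0.15, and Cdkn2c from 2.14 ± 0.07 to 0.49 ± 0.10. Cdkn1c, an imprinted kinase inhibitor gene, rose from 4.56 ± 0.04 to 11.2 ± 0.64 RPKM. Of 26 G1/S genes, 11 rose, among them Ccne1 (log2 1.15) and Mcm5 (0.67), and 8 fell, among them Ccnd1 (-0.74); the list was not called (adjusted p = 0.299).

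Genes with a miR-294 site in the 3' UTR were lower as a class. The median log2 change was -0.37 for 422 genes with the 8-base match, -0.21 for 1665 genes with AGCACTT, -0.21 for 384 genes with GCACTTA and -0.03 for 8764 genes without a match. Among genes with the 8-base match, 256 fell and 50 rose; 60.7% fell, against 33.3% of genes without a match. Camera gave an adjusted p of 2.73e-05 for all 2471 genes with a site (adjusted p = 0.0491 with an estimated correlation) and 7.46e-07 for the 8-base class (adjusted p = 0.0491 with an estimated correlation), over 4 classes. Relative to genes without a site, the 8-base class lay at -0.34 and -0.35 in the miR-294 libraries and at -0.08 and -0.07 in the siMbd2 libraries, where the CTR libraries lay at -0.04 and 0.04. The Cdkn1a 3' UTR holds AGCACTTA at chromosome 17, 29100500 to 29100507, and that of Rbl2 at chromosome 8, 91123830 to 91123837.

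**Figure D2:**
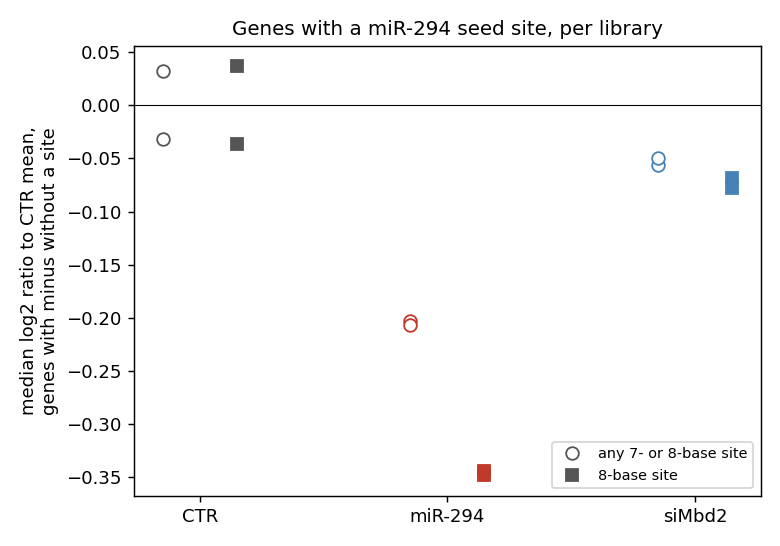
Median log2 ratio to the CTR mean of genes with a miR-294 site minus that of genes without one (vertical axis, log2), for each library by group; open circles are all 7- and 8-base sites and filled squares the 8-base site. Both miR-294 libraries lie below the others, at -0.34 and -0.35 for the 8-base site; the CTR values mirror each other because they are ratios to the mean of the same 2 libraries.

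Myc-responsive genes rose with miR-294, 35 of 40 with 1 lower, with a median log2 change of 0.70 (adjusted p = 1.95e-13). Adjusted over the list alone 35 rose, and the list had adjusted p = 0.541 with an estimated correlation. With quantile normalization its difference from other genes went from 0.76 to 0.50 (adjusted p = 3.14e-08). Srm, the spermidine synthase gene, rose from 54.2 ± 7.52 to 154 ± 1.65 RPKM, Odc1, which encodes ornithine decarboxylase of the same pathway, from 139 ± 4.39 to 321 ± 1.34, and Nme1 from 21.4 ± 1.46 to 45.4 ± 4.36. Of the MYC family and its partners, Mycn rose by 0.54 (log2) and Mycl by 1.15, while Mxd3, a MYC antagonist, changed by -1.08. Of these 11 genes 6 rose and 4 fell, and the list was not called (adjusted p = 0.418). Of 37 cytosolic ribosomal protein genes, 35 rose (36 adjusted over the list alone), such as Rplp0 (694 ± 72.8 to 1156 ± 27.8 RPKM), but with quantile normalization this list was no longer called (difference from other genes 0.08, adjusted p = 0.420). The median was 0.42 (adjusted p = 1.91e-10; adjusted p = 0.573 with an estimated correlation). Of random lists matched on expression and transcript length, 13.7% had a median as high, but ribosomal protein genes outside the list could be drawn into them.

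Metabolic genes did not move together. Of 22 glycolysis genes, 10 rose and 4 fell with miR-294 and the list was not called (adjusted p = 0.0594). It passed with median-of-ratios scaling (adjusted p = 0.0317), without CTR replicate 1 (adjusted p = 0.00758) and without miR-294 replicate 1 (adjusted p = 0.0493). Its difference from other genes went from 0.28 to 0.06 with quantile normalization (adjusted p = 0.729), 0.24 without CTR replicate 2 (adjusted p = 0.149) and 0.25 with a minimum mean of 5 RPKM (adjusted p = 0.134). Pkm, a pyruvate kinase gene, rose from 623 ± 67.2 to 1222 ± 17.5 RPKM (log2 0.98, adjusted p = 1.45e-05) and Aldoa, an aldolase gene, from 443 ± 40.4 to 850 ± 6.43, whereas Hk1 fell to 7.85 ± 0.37 RPKM (adjusted p = 1.47e-05). Hk2 rose by 0.32 (log2, adjusted p = 0.00130), and Ldha, the lactate dehydrogenase gene, rose by 0.29 (adjusted p = 0.00324), a call that ended with quantile normalization (0.05, adjusted p = 0.350). The glucose transporter gene Slc2a1 read 113 ± 7.76 RPKM in CTR and 114 ± 1.58 with miR-294 (adjusted p = 0.828), and was lower by -0.18 with quantile normalization (adjusted p = 0.0132). Of 49 nuclear genes of oxidative phosphorylation, 24 rose and 2 fell (22 and 1 adjusted over the list alone), but the list's call ended with quantile normalization (difference 0.03, adjusted p = 0.934). It had adjusted p = 1.38e-04, and adjusted p = 0.678 with an estimated correlation. Atp5g1 rose from 116 ± 19.8 to 221 ± 0.43 RPKM. Of 13 mitochondrially encoded genes, 7 fell and none rose (median -0.45, adjusted p = 0.160). Their difference from other genes, -0.33, was called with quantile normalization (-0.56, adjusted p = 0.0199). It was -0.65 without CTR replicate 1, which leaves the CTR library with the higher mitochondrial share (4.13% against 3.03%). The size of the fall thus depended on the CTR library used. Of 21 citric acid cycle genes, 4 rose and 9 fell, Idh2 from 156 ± 21.2 to 64.0 ± 0.54 RPKM (list adjusted p = 0.578, or 0.0275 with quantile normalization). Of 7 pentose phosphate genes, 3 rose and 2 fell (adjusted p = 0.860).

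Genes of the amino acid stress response driven by ATF4 rose with miR-294: 14 of 17 rose and none fell, also adjusted over the list alone (median 0.69, adjusted p = 2.21e-06). The list had adjusted p = 0.566 with an estimated correlation. They included Chac1 (7.56 ± 0.84 to 26.6 ± 0.24 RPKM), Trib3 (17.4 ± 0.74 to 34.2 ± 0.91) and the serine synthesis genes Phgdh (54.1 ± 4.30 to 102 ± 2.42) and Psph. Of 15 genes of MAPK feedback, 8 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.00586; adjusted p = 0.566 with an estimated correlation). Spry4 (16.0 ± 1.65 to 51.0 ± 1.46 RPKM), Etv4 (23.9 ± 1.80 to 72.3 ± 1.48) and Spry2 were among those that rose. Of 10 genes of the 2-cell-like state, a rare early-embryo-like state of ESC cultures, 9 rose, also adjusted over the list alone (adjusted p = 6.85e-04; adjusted p = 0.541 with an estimated correlation). Examples are Gm8300 (2.44 ± 0.66 to 6.50 ± 0.35 RPKM) and Zfp352 (0.54 ± 0.13 to 1.85 ± 0.08). Many of these genes exist in near-identical copies. The call ended with a minimum mean of 5 RPKM (adjusted p = 0.189), where the difference from other genes went from 0.73 to 0.46.

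Of 12 interferon-response genes, 8 fell and 2 rose with miR-294, also adjusted over the list alone (median -1.13, adjusted p = 0.0175). The list had adjusted p = 0.541 with an estimated correlation. Oasl2 fell by 2.42 on the log2 scale, Ifi35 fell from 9.90 ± 0.54 to 2.38 ± 0.45 RPKM and Isg15, a ubiquitin-like modifier, from 2.37 ± 0.28 to 0.41 ± 0.08. Of 16 epithelial genes, 8 fell and 3 rose; the junction genes Cldn3 (log2 -1.53), Cldn7 (33.5 ± 4.53 to 12.5 ± 0.02 RPKM) and Dsp fell (list adjusted p = 0.406). Of 15 mesenchymal genes, 9 fell, such as Vim (211 ± 27.7 to 93.0 ± 5.58 RPKM) and Cdh2, and 3 rose (list adjusted p = 0.160). Feeder fibroblast markers gave no call (1 of 5 rose and 2 fell, adjusted p = 0.709).

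Pluripotency genes split with miR-294. Pou5f1, the gene of OCT4, rose from 740 ± 71.9 to 1058 ± 1.75 RPKM (log2 0.52, adjusted p = 3.13e-04), while Nanog fell from 363 ± 12.7 to 208 ± 3.43 (log2 -0.80, adjusted p = 1.09e-05) and Sox2 from 275 ± 20.9 to 193 ± 2.26 (log2 -0.51, adjusted p = 1.76e-04). The nuclear receptor genes Nr5a2 (log2 1.21) and Nr0b1 (1.15) rose. Of 29 pluripotency genes, 16 rose and 8 fell (list adjusted p = 0.0630; 0.0327 without CTR replicate 2 and 0.0493 without miR-294 replicate 1). Of 10 genes of the DNA methylation machinery, 6 rose and 3 fell (adjusted p = 0.166), with Dnmt3a (22.3 ± 5.02 to 52.7 ± 0.15 RPKM) and Dnmt3b (32.3 ± 0.77 to 75.9 ± 1.47) up and the demethylase gene Tet3 down (log2 -0.83). Dgcr8 read 7.96 ± 0.67 RPKM in CTR and 6.90 ± 0.34 with miR-294 (adjusted p = 0.0984; 0.0234 without CTR replicate 1, log2 -0.26), so the gene-level value does not show the described deletion.

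In all, 3162 genes rose and 4204 fell with miR-294 out of 11428 tested, of which 1090 and 1906 changed at least 1.5-fold. Of the changed genes 42.9% rose with the deposited scaling, 49.4% with median-of-ratios scaling and 51.3% with quantile normalization, so the excess of lower genes among all called genes shrank with median-of-ratios scaling (3684 higher, 3780 lower) and turned with quantile normalization (3648 and 3469). Among larger changes it was smaller but kept, in runs added after the results were seen. At 1.5-fold 1283 genes were higher and 1377 lower with quantile normalization, and 1344 and 1646 with median-of-ratios scaling. At 2-fold 26.3% were higher with the deposited scaling, 34.1% with median-of-ratios scaling and 40.8% with quantile normalization.

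**Figure D3:**
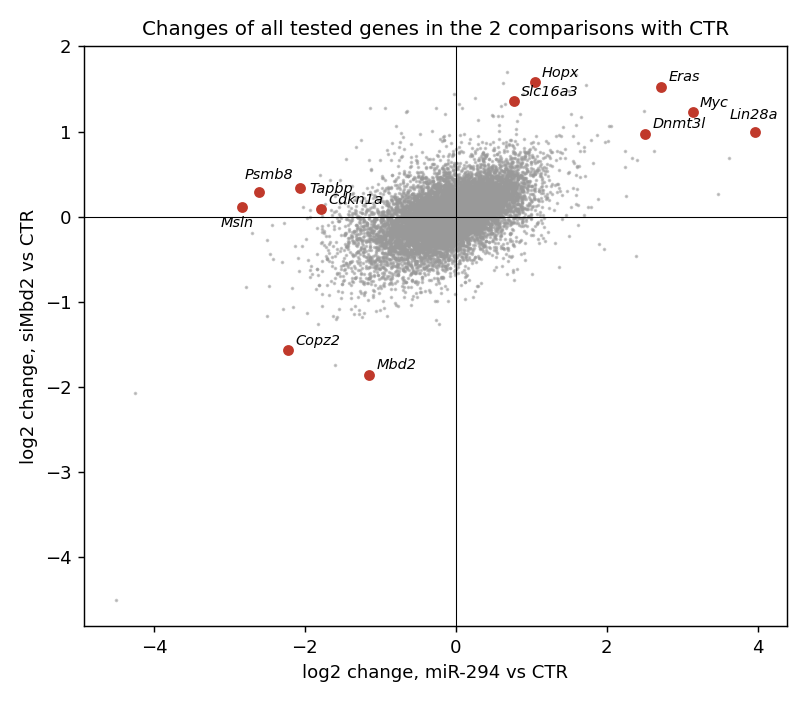
Log2 change with siMbd2 (vertical axis) against log2 change with miR-294 (horizontal axis), both relative to CTR, for all 11428 tested genes, with named genes labelled. Both axes use the same CTR libraries; 1367 genes rose in both contrasts and 1215 fell in both.

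The comparison of siMbd2 with CTR asks what lowering Mbd2 does without the microRNA. Besides Mbd2, genes that fell were Pter (18.1 ± 0.74 to 4.77 ± 0.99 RPKM, log2 -1.74) and Pecam1, which encodes an adhesion molecule of ESCs and endothelium (51.8 ± 2.55 to 22.3 ± 1.62, log2 -1.18). AU015836 rose from 10.5 ± 0.39 to 35.6 ± 0.32 RPKM (log2 1.67), Hopx, a homeodomain cofactor gene, from 5.11 ± 0.49 to 17.2 ± 1.19 (log2 1.58), and Slc16a3, a lactate exporter gene, from 20.3 ± 2.47 to 53.4 ± 1.32 (log2 1.36). Myc rose from 2.12 ± 0.40 to 6.31 ± 0.85 RPKM (log2 1.23, adjusted p = 3.95e-04). Glycolysis genes and Myc-responsive genes rose as groups at the preset correlation (adjusted p = 0.932 for both lists with an estimated correlation), by less than 1.5-fold for the median gene. Fry called the Myc-responsive genes (adjusted p = 0.0334) but not glycolysis (adjusted p = 0.052).

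Tnfsf9 (1.28 ± 0.06 to 5.78 ± 0.02 RPKM), Fgf17 (2.48 ± 0.33 to 9.16 ± 0.69), Eras (3.76 ± 0.24 to 12.7 ± 0.08), Apol6 (log2 1.48), Madcam1 (1.35 ± 0.37 to 5.35 ± 0.03), Zc3h12a (3.47 ± 0.46 to 11.2 ± 1.87) and Itga9 (4.98 ± 0.54 to 13.9 ± 0.21) completed the largest increases with siMbd2. Tnfsf9 and Fgf17 encode secreted or surface ligands, and Zc3h12a an endoribonuclease that limits inflammatory mRNAs. Larger decreases included Copz2 (8.87 ± 1.46 to 2.34 ± 0.63 RPKM), Ffar3 (7.80 ± 1.66 to 2.66 ± 0.28), 4930447C04Rik (41.2 ± 9.29 to 17.0 ± 1.48), Myb (5.78 ± 0.28 in CTR, adjusted p = 2.42e-04), Aldh1b1 (27.5 ± 3.75 to 11.7 ± 1.85) and St6gal1 (15.8 ± 1.54 to 6.62 ± 0.85). Adjusted p-values of these genes ran from 4.02e-05 for AU015836 to 7.73e-04 for 4930447C04Rik.

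Of 22 glycolysis genes, 12 rose and 1 fell with siMbd2 (12 and 2 adjusted over the list alone), with a median log2 change of 0.29 (adjusted p = 0.00216; adjusted p = 0.932 with an estimated correlation). Ldha rose from 347 ± 21.4 to 517 ± 13.1 RPKM (log2 0.58, adjusted p = 5.86e-04), Slc2a1 from 113 ± 7.76 to 153 ± 2.33 (log2 0.43, adjusted p = 0.00165) and Pfkl, a phosphofructokinase gene, from 36.7 ± 6.10 to 62.4 ± 1.94, while the glucose transporter gene Slc2a3 fell from 260 ± 9.96 to 171 ± 4.88. Pkm rose by 0.36 (adjusted p = 0.00844), a call that ended with quantile normalization (0.15, adjusted p = 0.12). The call also ended without siMbd2 replicate 1 or 2, where the change stayed at 0.35 and 0.36. Hk2 rose by 0.33 (adjusted p = 0.00369), a call that ended without siMbd2 replicate 2, where the change was still 0.31.

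Of 40 Myc-responsive genes, 25 rose and 1 fell with siMbd2, also adjusted over the list alone, such as Nme1 (21.4 ± 1.46 to 34.7 ± 0.74 RPKM), Nme2 and Srm. Their median was 0.22 (adjusted p = 8.04e-05; adjusted p = 0.932 with an estimated correlation). MAPK feedback genes rose, 9 of 15 with none lower, also adjusted over the list alone (adjusted p = 0.00216; adjusted p = 0.932 with an estimated correlation). Among them were Ier3 (10.2 ± 0.01 to 22.3 ± 0.50 RPKM), Etv4 (23.9 ± 1.80 to 47.1 ± 4.17) and Spry4. Of 16 epithelial genes, 9 rose and 2 fell, the same adjusted over the list alone (adjusted p = 0.0180; adjusted p = 0.932 with an estimated correlation; 0.0898 without CTR replicate 2). Krt19 rose from 2.98 ± 0.10 to 6.34 ± 0.05 RPKM, Cldn6 from 10.5 ± 1.26 to 19.4 ± 0.45 and Grhl2, an epithelial transcription factor gene, from 4.32 ± 0.54 to 7.94 ± 0.61. Of 37 ribosomal protein genes, 12 rose and none fell (13 and 0 adjusted over the list alone), but the list's call ended with quantile normalization (difference 0.01, adjusted p = 0.953). It had adjusted p = 0.00216, and adjusted p = 0.932 with an estimated correlation. Of the lists called here at the preset correlation, fry called the Myc-responsive and MAPK feedback genes (adjusted p = 0.0334 for both). It did not call the glycolysis (adjusted p = 0.052), epithelial (0.061) and ribosomal (0.177) lists.

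Most other groups did not pass as lists with siMbd2 by camera at the preset correlation, to which the list p-values of this paragraph belong. Fry called the described targets (lower, adjusted p = 0.0374), feeder fibroblast markers (lower, 0.0374), mesenchymal genes (higher, 0.0407) and DNA methylation genes (higher, 0.0334). It did not call the interferon-response (adjusted p = 0.193) and oxidative phosphorylation (0.230) lists. Of 17 described miR-290 family targets, Mbd2 and 4 others fell, 2 rose and 10 did not pass (adjusted p = 0.130). Cdkn1a read 58.1 ± 4.70 RPKM in CTR and 61.8 ± 3.16 with siMbd2 (adjusted p = 0.440). Lats2 had a log2 change of 0.16 (adjusted p = 0.167) and Rbl2 of -0.14 (adjusted p = 0.272). Casp2 had a log2 change of -0.19 (adjusted p = 0.0587), which passed with median-of-ratios scaling (adjusted p = 0.0412), with quantile normalization (adjusted p = 0.0186) and without CTR replicate 2 (adjusted p = 0.0333). Mycn read 65.4 ± 1.20 and 70.5 ± 0.76 RPKM (adjusted p = 0.148; 0.0395 without CTR replicate 1) and Dgcr8 7.96 ± 0.67 and 7.29 ± 0.07 (adjusted p = 0.354). Of 12 interferon-response genes, 3 rose, with Isg15 from 2.37 ± 0.28 to 5.28 ± 0.30 RPKM and Ddx58 from 15.1 ± 1.13 to 26.2 ± 1.56, and 2 fell (adjusted p = 0.899). Of 15 mesenchymal genes, 7 rose, with S100a6 from 52.5 ± 1.85 to 128 ± 3.15 RPKM and Tagln from 11.8 ± 0.79 to 22.8 ± 1.20, and 5 fell (adjusted p = 0.740). Among 10 DNA methylation genes only Dnmt3l (log2 0.97) and Dnmt3b (0.53) rose (list adjusted p = 0.715). Sox2 fell by 0.42 (log2, adjusted p = 0.00213) and Nanog by 0.33 (adjusted p = 0.00369). The Nanog call ended without siMbd2 replicate 2, at a log2 change of -0.29. Pou5f1 rose by 0.33 (adjusted p = 0.00933), a call that ended with quantile normalization (0.15, adjusted p = 0.0547). The call also ended without siMbd2 replicate 1 or 2, where the change was still 0.36 and 0.31. Of 49 oxidative phosphorylation genes 11 rose and 2 fell, a list called only without CTR replicate 1 (adjusted p = 0.00508). Genes with a miR-294 site did not pass as a class (adjusted p = 0.104). Their unadjusted camera p was 0.0522, or 0.00808 without CTR replicate 1, 0.0431 without siMbd2 replicate 2 and 0.299 without CTR replicate 2. Against genes matched on 3' UTR length the camera p was 0.866, and the difference went from -0.057 to -0.0045. Of 5 feeder fibroblast markers 4 fell and none rose (list adjusted p = 0.0666; 0.0309 without siMbd2 replicate 2).

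With siMbd2, 2231 genes rose and 1702 fell, of which 371 and 351 changed at least 1.5-fold. These counts depended on which libraries set the shared estimate of spread. With only the siMbd2 and CTR libraries in the model, 1766 rose and 1343 fell. The counts also moved when single libraries were left out, which changes that estimate too. A search over 7-base words of the 3' UTRs in this same contrast picked GAGCGAG as the lowest, so the shares given next are no independent support. The 494 genes that hold it fell more often than others (23.5% against 14.6%, not adjusted for 3' UTR length, base content or expression). Without them 2170 genes rose and 1580 fell.

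The direct comparison of miR-294 with siMbd2 sets the microRNA against the siRNA. The CTR libraries are not compared in it. They enter through the shared estimate of spread, the filter on mean RPKM and the alternative scalings. Myc was higher with miR-294 (26.5 ± 0.69 against 6.31 ± 0.85 RPKM, log2 1.91, adjusted p = 8.59e-06), although Mbd2 mRNA was also higher there. Spink3 (log2 3.21), Lin28a (2.97), Calca (2.93) and Rhox5, an X-linked homeobox gene of the germline (72.0 ± 0.39 against 13.5 ± 0.97 RPKM), were higher with miR-294. Msln (8.70 ± 0.18 against 73.9 ± 3.06 RPKM), Psmb8 (0.74 ± 0.39 against 11.8 ± 0.01), Tapbp, a chaperone gene of antigen presentation (14.5 ± 1.29 against 80.5 ± 0.35), and Ubd, an inducible ubiquitin-like gene (15.2 ± 1.10 against 74.5 ± 0.35), were lower.

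Further genes higher with miR-294 than with siMbd2 were Pla2g1b (log2 2.84), 1110002L01Rik (2.22), Axin2, a WNT target gene (7.28 ± 0.16 against 1.04 ± 0.15 RPKM), Apoa2 (1.96) and Bmp4 (1.85). Those lower were Mmp23 (log2 -2.52), the chemokine gene Cxcl10 (1.19 ± 0.59 against 10.6 ± 2.04 RPKM), Plagl1 (-2.34), Syde1 (-2.30), Erap1 (-2.23) and Gsdmd, a pore-forming protein gene of pyroptosis (3.94 ± 0.13 against 21.6 ± 0.62 RPKM). Glycolysis genes differed in both directions, with 6 higher and 9 lower (list adjusted p = 0.912). Pkm was higher with miR-294 (log2 0.62, adjusted p = 2.12e-04), whereas Ldha (-0.29, adjusted p = 0.00352), Slc2a1 (-0.42, adjusted p = 5.85e-04) and Slc16a3 (-0.59) were lower; Hk2 did not differ detectably (-0.01, adjusted p = 0.884). Nanog was lower with miR-294 (log2 -0.47, adjusted p = 2.25e-04).

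Lists higher with miR-294 than with siMbd2 were the Myc-responsive genes (33 of 40 higher, 1 lower, adjusted p = 2.47e-12), the ATF4 response (13 of 17, 1 lower, adjusted p = 3.34e-08) and the 2-cell-like genes (7 of 10, adjusted p = 2.46e-04). The ribosomal proteins (28 of 37, adjusted p = 1.94e-08), oxidative phosphorylation (21 of 49, 1 lower, adjusted p = 0.00137) and G2/M genes (12 of 23, 3 lower, adjusted p = 0.0270) were called too, but not with quantile normalization (adjusted p = 0.352, 0.969 and 0.274). The differences from other genes went from 0.38, 0.24 and 0.23 to 0.07, 0.01 and 0.10. Median-of-ratios scaling kept these calls, but with 1 factor per library it shifts nearly all genes alike and could hardly change such differences. The G2/M call also ended without genes holding GAGCGAG (adjusted p = 0.0633), an analysis added after the results were seen, although the difference was still 0.20. Also called were MAPK feedback (8 of 15, 3 lower, adjusted p = 0.0423) and methylation-silenced germline genes (9 of 17, 4 lower, adjusted p = 0.0423), but not with quantile normalization (adjusted p = 0.0671 for both) or median-of-ratios scaling (adjusted p = 0.0758 and 0.103). Their differences barely moved, from 0.35 (MAPK) and 0.34 (germline) to 0.34 and 0.38 with the former and 0.35 and 0.34 with the latter. These MAPK and germline calls also ended with only the 2 groups compared (adjusted p = 0.0529 for both), at unchanged differences. With a minimum mean of 5 RPKM they ended too (adjusted p = 0.0811 and 0.593). There the MAPK difference stayed at 0.35 and the germline one fell to 0.16. The MAPK call also ended without a filter (0.31, adjusted p = 0.0612). Lists lower with miR-294 were the described targets (14 of 17 lower, 1 higher, adjusted p = 1.61e-05), epithelial genes (10 of 16, adjusted p = 0.00231) and interferon-response genes (8 of 12, adjusted p = 0.00306). So were mesenchymal genes (9 of 15, 2 higher, adjusted p = 0.0224) and cell cycle inhibitors (8 of 9, 1 higher, adjusted p = 0.0280). Adjusted over the list alone, 35, 14, 8, 30, 19, 12, 8 and 10 members of the higher lists were higher, in this order, and 14, 10, 8, 9 and 8 members of the lower lists lower. None of these calls held with an estimated correlation: the lowest adjusted p = 0.412 with an estimated correlation. Fry called all of these lists except oxidative phosphorylation (adjusted p = 0.105). The MAPK and germline calls ended without CTR replicate 1 or 2, at unchanged differences of 0.35 and 0.34, since the CTR libraries are not compared here. The germline call also ended without miR-294 replicate 2 (difference 0.32) and the MAPK call without siMbd2 replicate 1 (difference 0.29). The 2-cell-like (adjusted p = 0.168) and cell cycle inhibitor (0.0705) calls ended with a minimum mean of 5 RPKM, and the mesenchymal call (0.142) without a filter. The 2-cell-like difference went from 0.71 to 0.38 and the mesenchymal one from -0.42 to -0.26. That of the cell cycle inhibitors did not shrink (-0.53 to -0.56). Higher genes of these lists were Chac1 (log2 1.68), Nupr1 (1.22) and Trib3 (1.13) of the ATF4 response and Gnl3 (0.97) of the Myc-responsive genes. Lower were Cldn3 (-1.54), Cldn7 (-1.54) and Jup (-1.25) of the epithelial genes, and Isg15 (-2.16) and Oasl2 (-1.93) of the interferon response.

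**Figure D4:**
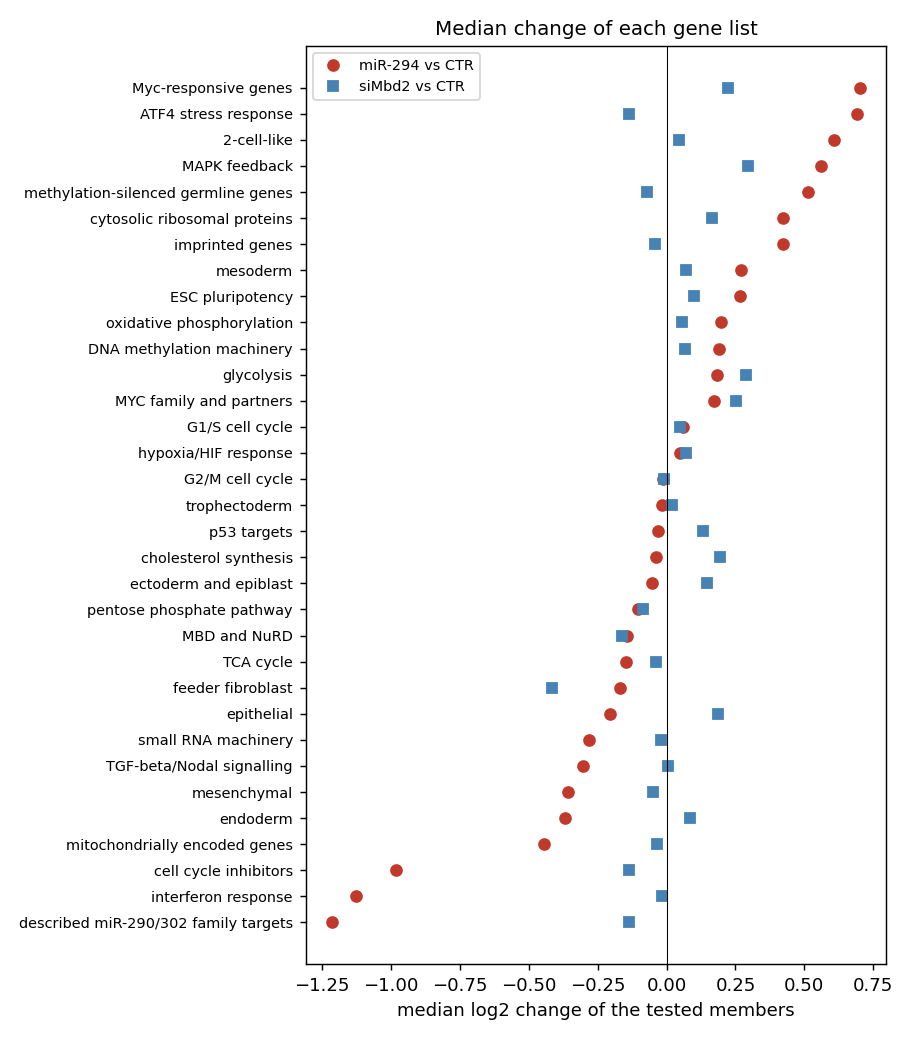
Median log2 change of the tested members of each of the 33 gene lists (horizontal axis) against CTR, with miR-294 (circles) and siMbd2 (squares). The described targets had the lowest median with miR-294 (-1.21) and the Myc-responsive genes the highest (0.70). The calls of the ribosomal and oxidative phosphorylation lists with miR-294 ended with quantile normalization.

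Between miR-294 and siMbd2, 2500 genes were higher and 4061 lower with miR-294, of which 588 and 1634 differed at least 1.5-fold. With only these 2 groups in the model the counts were 3077 and 4677. Leaving out any single miR-294 or siMbd2 library lowered both counts. The share higher was 38.1% with the deposited scaling, 47.7% with median-of-ratios scaling and 51.5% with quantile normalization, which moved the median of all genes by 0.11 (log2). At 1.5-fold more genes were still lower, 1037 against 853 higher with quantile normalization and 1324 against 805 with median-of-ratios scaling.

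The last comparison asks whether the treatments changed the same genes. Of the genes called in both, 1367 rose in both and 1215 fell in both, against 617 and 626 for independent lists. Another 101 rose with miR-294 and fell with siMbd2, and 272 did the opposite, against 471 and 821. Myc, Lin28a, Dnmt3l, Eras and Etv4 rose in both, and Mbd2, Aldh1b1, Lefty1, Lefty2, Nanog and Sox2 fell in both. Of the genes that rose in both, 587 rose more with miR-294, 84 rose more with siMbd2 and 696 were not called between the treatments. Of those that fell in both, 592 fell more with miR-294, 51 fell more with siMbd2 and 572 were not called.

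Both contrasts share the CTR libraries, which by itself makes their changes alike. Simulated groups without change, set against shared CTR libraries that were simulated too, had a mean correlation across genes of 0.497, where 0.521 was observed. The simulated correlation follows from the shared control whatever the size of the changes, so it cannot show how much of the likeness is noise. The covariance was 0.0906, where simulated groups gave at most 0.0050. They had at most 1 gene called higher in both, where 1367 were observed. The simulated genes varied independently of each other and equally in all groups. In the data the CTR pair varied most (SD of the log2 difference 0.193, against 0.124 for miR-294 and 0.128 for siMbd2). The simulated limits, here and for the split CTR libraries below, may thus be too narrow. Genes are not independent replicates. In an analysis added after the results were seen, each contrast was therefore given its own CTR library. With CTR replicate 1 for miR-294 and 2 for siMbd2, 1640 genes rose in both and 1319 fell in both, against 922 and 840 for independent lists. With the CTR libraries exchanged, 1453 rose and 1313 fell in both, against 696 and 758. Genes that rose with miR-294 and fell with siMbd2 numbered 230 and 223 in these runs, against 569 and 649, and 794 and 296 did the opposite, against 1360 and 814. The correlation across genes was 0.402 and 0.481, where simulated groups without change gave at most 0.0467 and 0.0454, and 61.1% and 66.5% of genes changed in the same direction, where they gave at most 51.2% and 51.1%. The shared CTR values were thus not the whole of the overlap. What the CTR wells received is not stated, so a response to transfected RNA as such was not separated from a response to lower Mbd2. The overlap also moved with single libraries: 2059 genes rose in both without CTR replicate 1, 706 rose and 623 fell without siMbd2 replicate 1, and 574 rose and 433 fell without siMbd2 replicate 2.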

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

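The runs with a 2-fold threshold, with a fold threshold and another scaling together, without genes listed at 0, without genes holding GAGCGAG and with the CTR libraries split between the contrasts were chosen after the results were seen. Of 126 recomputed counts of changed genes, 108 stayed within 1.5 times the reported count. Of 1776 list results, 1728 kept their side of the threshold, 27 lost a call, 20 gained one and 1 reversed. Most of these list results had no call to lose. The robust option did not enter the list tests, so its 99 list results repeat the main ones. For named genes the numbers were 8481 of 9039, 537, 20 and 1. The sign changed in 54 list results and 8 of named genes, all but the reversed ones without a call in either setting. The depth of the libraries is unknown, and genes at low RPKM are the least precise. With a replicate block (replicate numbers matched across groups) 3263 genes were higher and 4342 lower in miR-294 vs CTR, 2433 and 1872 in siMbd2 vs CTR, and 2612 and 4203 in miR-294 vs siMbd2. With only the 2 groups compared in the model, 2915 genes were higher and 3920 lower in miR-294 vs CTR. The counts were then 1766 and 1343 in siMbd2 vs CTR, and 3077 and 4677 in miR-294 vs siMbd2. The CTR pair was the noisiest and is part of the shared spread of the main model.

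Thresholds lowered the counts by construction. At 1.5-fold they were 1090 higher and 1906 lower (miR-294 vs CTR), 371 and 351 (siMbd2 vs CTR), 588 and 1634 (miR-294 vs siMbd2), with 186 higher and 224 lower in both. At 2-fold they were 220 and 616, 40 and 31, 122 and 434, with 12 and 23 in both. A minimum mean of 5 RPKM, which tests fewer genes, left 1101 genes lower with siMbd2 and 779 lower in both. Leaving out 1 library gave 848 to 3350 genes higher and 562 to 2085 lower with siMbd2, and 574 to 2059 higher and 433 to 1516 lower in both. The highest count came without CTR replicate 1 for genes higher and without CTR replicate 2 for genes lower, and the lowest without siMbd2 replicate 2.

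The difference between genes with and without a miR-294 site with siMbd2 (-0.057, camera over 2471 genes, just over the unadjusted threshold) passed it with a minimum mean of 5 RPKM (-0.058), with any annotated 3' UTR (-0.057), and without CTR replicate 1 (-0.083) or siMbd2 replicate 2 (-0.058); it ran from -0.083 to -0.031 without 1 library. Against genes matched on 3' UTR length it was -0.0045 with siMbd2 and -0.169 with miR-294. The glycolysis list in miR-294 vs CTR (difference from other genes 0.28, adjusted p = 0.0594) passed with median-of-ratios scaling (0.29, adjusted p = 0.0317), without genes holding GAGCGAG (0.31, adjusted p = 0.0323), without CTR replicate 1 (0.33, adjusted p = 0.00758) and without miR-294 replicate 1 (0.29, adjusted p = 0.0493). It fell to 0.06 with quantile normalization (adjusted p = 0.729) and ran from 0.24 to 0.33 without 1 library. Slc2a1 in miR-294 vs CTR turned from 0.02 to -0.18 with quantile normalization. The mitochondrially encoded genes list in siMbd2 vs CTR turned from -0.02 to 0.30 without CTR replicate 2 and stood at -0.34 without CTR replicate 1. Apart from the thresholds and filters, the cause was not tested.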

Other observations

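The tests of GAGCGAG, of the interferon-response genes, of Myc and of the antigen presentation genes were chosen after the results were seen; the tests of the ribosomal list were set before theirs. A list of 10 genes of antigen presentation by MHC class I was drawn up after seeing Psmb8 and Tapbp, which it holds, and was not tested against other genes. All 10 fell with miR-294 (median log2 change -0.99), with Tapbp from 63.5 ± 1.52 to 14.5 ± 1.29 RPKM, B2m, the light chain gene, from 18.3 ± 3.66 to 11.1 ± 0.55, and the peptide transporter gene Tap1 from 3.92 ± 0.74 to 1.17 ± 0.02 (SD, n = 2). With siMbd2 4 of the 10 rose and 6 were not called, Erap1 among them (log2 -0.28, adjusted p = 0.0675): H2-K1 rose from 17.3 ± 3.02 to 28.2 ± 1.45 RPKM, H2-D1 from 12.3 ± 2.55 to 21.4 ± 0.91, B2m to 25.6 ± 1.41 and Tapbp to 80.5 ± 0.35.

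Imprinted and germline genes changed in both directions with miR-294. Of 17 imprinted genes 9 rose, such as Phlda2 (8.62 ± 0.99 to 44.3 ± 2.21 RPKM) and Peg10 (36.1 ± 0.44 to 83.3 ± 0.03), and 7 fell, such as Plagl1 (29.6 ± 1.06 to 4.66 ± 0.29); the list was not called (adjusted p = 0.252). Of 17 germline genes silenced by DNA methylation, 11 rose, such as Rhox5 (17.8 ± 1.63 to 72.0 ± 0.39 RPKM) and Tex19.1 (34.0 ± 1.86 to 91.6 ± 1.38), and 4 fell, such as Rhox9 (adjusted p = 0.0797; 0.0254 without a filter on low values). With siMbd2 3 imprinted genes rose and 2 fell, Peg3 from 14.3 ± 0.30 to 6.14 ± 0.08 RPKM, and 3 germline genes rose and 5 fell (adjusted p = 0.715 for both lists). Other lists without a call with miR-294 were the MBD and NuRD genes (4 rose, 9 fell of 19), p53 targets (5 and 7 of 19), TGF-beta and Nodal genes (5 and 11 of 21), small RNA machinery (3 and 8 of 14, with Ago1 at a log2 change of -1.15), hypoxia genes (4 and 5 of 15) and cholesterol synthesis (5 and 2 of 19).

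Genes that hold GAGCGAG in the 3' UTR were lower with siMbd2. In a search over 15857 words of 7 bases this word ranked lowest: 494 genes carried it, with a mean residual log2 change of -0.086 (SE 0.013), and it lay at -0.084 and -0.089 in the siMbd2 libraries. The word was picked as the lowest, so this SE over genes does not allow for the search. Base composition as the whole cause is argued against: 59 other words of equal composition had a median of -0.0096 (SD 0.0159 across words, lowest -0.0474). That GAGCGAG lies below them is no support, since it was picked as the lowest. Noise of the shared CTR libraries is argued against by miR-294 against CTR, where these genes lay at -0.0013 (SE 0.0227). They were 0.0843 higher with miR-294 than with siMbd2, but the siMbd2 libraries picked the word, so this value is no separate support. Partial matches of the siRNA to other mRNAs may account for the lower values of these genes. The word occurs in 3 of 5 annotated Mbd2 transcripts (chromosome 18, 70622593 to 70622599), but 16.4% of all words occur in Mbd2 transcripts. The siRNA sequence is not given in the sources used here, so such matches were not searched for. miR-294 lowered Mbd2 mRNA too, though less (log2 -1.15 against -1.86), without a like fall of these genes. An effect of lower Mbd2 would thus need the lower level reached with siMbd2, or an offset by other changes with miR-294, and neither was tested.

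Interferon-response genes were lower with miR-294. A response alike for any transfected RNA or reagent is argued against by the direct contrast with siMbd2, transfected at the same dose. There the list median was -0.96. This contrast cannot exclude a response that differs between the microRNA mimic and the siRNA. Feeder fibroblasts in the other libraries are argued against by collagen: Col1a1 reached 0.29 RPKM at most in any library. With siMbd2 against CTR the median was -0.02, with 3 genes higher and 2 lower. Direct targeting stays open: 5 of the 8 lower genes hold a miR-294 site in the longest 3' UTR, against 29.8% of the 4155 other genes lower with miR-294 (one-sided Fisher's exact p = 0.0569). Isg15, Oasl1 and Ifitm3 hold none there.

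Ribosomal protein genes were higher with miR-294 (median 0.42). Of 10000 random lists matched on expression level and transcript length, 13.7% had a median as high, and their typical median was 0.36. Only the listed genes were kept out of the draw, so other ribosomal protein genes could be drawn. Whether expression level and transcript length account for the rise thus stays open. Scaling between libraries could account for the rise. The list's median relative to all genes went from 0.50 with the deposited scaling to 0.043 with quantile normalization. Median-of-ratios scaling has 1 factor per library and shifts nearly all genes alike. It therefore cannot test this, and the mean difference from other genes stayed (0.54 against 0.53). Only a scaling that varies with expression level could change it. A biological difference caused by miR-294 was not excluded.

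A hypothesis that the loss of Mbd2 mRNA alone accounts for the rise of Myc with miR-294 was tested with the direct contrast. Myc was higher with miR-294 than with siMbd2 (log2 1.91, SE 0.115) while Mbd2 mRNA was higher too (0.71), in both libraries of each group, which argues against Mbd2 mRNA as the whole cause. Mbd2 protein was not measured, so its level may differ from that of the mRNA.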
